A study of Mus musculus with 6 samples.

How the data were processed

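RNA was measured in 6 libraries of sorted memory B cells, 3 from DAF KO and 3 from wild-type donors. Per the labels' protocols, CD45.1/2 recipient mice received an equal mix of both donors' B cells, were immunized with NP-OVA by intraperitoneal injection, and gave spleen cells 4 weeks later. Per the series design, the sort kept B220+ IgD- CD38+ GL7- cells with a lambda light chain that bound NP, and each replicate pooled 2 to 3 mice. The labels differ on the congenic marker of the wild-type cells, CD45.1 in the treatment protocol and CD45.2 in the design text, which gives CD45.2 for both genotypes. Libraries were made from 0.5 ng of total RNA with the SMART-Seq v4 PLUS kit, which amplifies full-length cDNA, per the labels' protocols. All libraries carry the same batch date in the labels.

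The authors deposited salmon estimated counts per gene, which need not be whole: 23.2% of the values were not. Library totals were 48398715 to 64289625 estimated counts. The submitters' processing notes name FastQC, Trimmomatic, STAR 2.7.10a and DESeq2 1.26.0, and the genome builds GRCm39, mm10 and GRCm38, without saying which step used which. The version of salmon, the annotation and the strand setting are not given in the sources used here. Without a stated strand, reads of genes that overlap on opposite strands cannot be told apart, and reads of near-identical genes can be split between them. Of the 54347 genes in the table, 99.53% were found by ID without version in GENCODE M21, and 98.09% with version. Positions and gene types were taken from that annotation, on GRCm38, by this match of IDs, and gene names were those deposited with the counts. Sorting, amplification and PCR come before the counts, so abundant transcripts are measured more precisely than rare ones, and a gene-level sum cannot tell which exons of a targeted gene were read.

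Estimated counts were rounded to whole numbers. Genes were kept by filterByExpr (minimum count 10 and total 15), which left 15043. Differences were tested in R 4.3.3 with edgeR 4.0.16, TMM factors and the quasi-likelihood test (glmQLFit with legacy=FALSE and robust=TRUE), with genotype as the only term and Benjamini-Hochberg adjustment at 0.05. CPM were scaled by the TMM-adjusted library size, except those of cell type markers and of Xist and Ddx3y, which were scaled by the library total alone. Values are given as mean ± SD, and log2 fold changes as DAF KO against wild type with 95% intervals where printed. The biological coefficient of variation was 0.337. Gene lists were tested with camera of limma 3.58.1, two-sided, with a preset correlation of 0.01 and adjustment over 25 lists with at least 3 tested members, and again with an estimated correlation and with fry. With so few libraries the version with an estimated correlation is the weaker test. A call lost there does not by itself show correlated members. The fry test for changes in either direction can pass on 1 strongly changed member, and it passed only for lists with a called gene. There were 20 gene lists and 7 lists of cell type markers. Immunoglobulin shares were compared with exact two-sided permutation tests over 20 arrangements. Replicates differed by more than counting noise, with a chi-square per degree of freedom of 32.5 to 54.3 between libraries of a group. Amplified reads can exceed counting noise too, so this did not tell separate pools from repeat libraries of 1 RNA. Heavy chain variable genes high in a single library, 7 genes in 5 libraries, argue against repeat libraries. Ighv10-1, for instance, took 7.37% of these counts in wild-type replicate 2 against a median of 0.268% elsewhere. The p-values measure the spread between these pools of mice. PCR reads without molecular identifiers are not independent molecules, so the floor of 3 counts covers counting error only.

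Lists, markers, the tests of genes, lists and immunoglobulin shares, and the rule for named genes were fixed before the data were examined. The tests of gene position, of the Cd55 RNA left and of handling in the closing section were not. The rule took Cd55 and Cd55b, up to 14 genes per direction with the smallest p among those past the threshold with an absolute log2 fold change of at least 1 and groups that did not overlap, without immunoglobulin variable segments and provisional names. Where fewer passed, up to 6 more per direction by unadjusted p were named as values. From each list it took the called members, up to 6, or else the 2 with the smallest p, and it added Ighv1-72, Iglv1, the heavy chain constant genes and Ptprc.

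The script was tested on simulated data for this comparison, with the real means, library sizes and dispersions and 200 changed genes in each of 10 runs (14427 to 14494 genes tested). It recovered 34.3% of genes changed 1.5-fold, 68.5% of those changed 2-fold and 86.2% of those changed 4-fold. Of 1373 calls in these runs, 115 (8.38%) were false, above the nominal rate. Camera found a simulated list shifted by 0.50 (unadjusted p of 6.15e-34) and not an unshifted one (unadjusted p of 0.833). Simulated genes were drawn independently, whereas real lists had estimated correlations of up to 0.71, so false calls among correlated genes were not tested. Alternatives were RLE and upper quartile factors, 2 other count filters, DESeq2 1.42.0, limma-voom, no robust estimation, the replicate number as a block, immunoglobulin genes or chromosome 1 neighbours left out, each library left out in turn, and, added after the data were seen, all chromosome 1 genes left out with or without the first 20 Mb of chromosome 17. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.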

Results

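Transcripts were counted in memory B cells from mouse spleen that lacked decay-accelerating factor (DAF, also called CD55), a membrane protein that limits complement activation, and in wild-type memory B cells. B cells of both genotypes had been transferred together, in equal parts, into recipient mice 1 day before immunization with NP-OVA, a hapten coupled to ovalbumin. Hapten-binding memory B cells were sorted 4 weeks later. Each genotype was represented by 3 libraries, and each library came from a pool of 2 to 3 mice. The libraries held 48398715 to 64289625 estimated counts, and 19367 to 20876 genes had at least 1 count in a library. Cd74, the invariant chain of MHC class II, took the largest share of any gene, 2.68% to 2.83% of a library. Mitochondrially encoded transcripts took 2.33% to 2.59% and immunoglobulin genes 2.13% to 2.27%. The comparison between the genotypes asks how loss of DAF alters the expression programme, proliferation and antibody repertoire of memory B cells.

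Cd55, the targeted gene, was lower in every DAF KO library than in every wild-type library. Its level was 196, 118 and 136 CPM in DAF KO replicates 1, 2 and 3, and 463, 337 and 379 CPM in the wild-type replicates. The group means were 150 ± 40.9 and 393 ± 63.8 CPM (SD, n = 3 each), a log2 fold change of -1.40 with a standard error of 0.18 (edgeR adjusted p = 0.0253). The DAF KO libraries thus held Cd55 RNA at 38.1% of the wild-type level, with at most 49.9% in a single library. Cd55 (ENSMUSG00000026399.12) lies on chromosome 1 from 130439027 to 130462744 (GRCm38), and the value sums all its annotated exons. Its neighbour and close paralog Cd55b, on chromosome 1 from 130388537 to 130423009, fell from 1.81 ± 0.437 to 0.110 ± 0.0661 CPM, 6.09% of its wild-type level (log2 fold change -4.01, SE 0.57, edgeR adjusted p = 0.013). Reads of the 2 genes can be shared, which makes the low Cd55b value uncertain. Leaving out any library other than DAF KO replicate 1 took the adjusted p of Cd55 above the threshold, to between 0.0585 and 0.186, with log2 fold changes from -1.25 to -1.50.

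DAF KO memory B cells differed from wild-type cells in few genes, among them the chemokine receptor genes Ackr3 and Ccr6, the fatty acid oxidation gene Acadl and the antiproliferative gene Btg2. Ackr3, an atypical receptor of the chemokine CXCL12, rose from 59.8 ± 10.9 to 197 ± 35.4 CPM, a 3.32-fold difference (edgeR adjusted p = 0.00307). Acadl, a mitochondrial dehydrogenase of long-chain fatty acid oxidation, rose from 98.5 ± 1.20 to 216 ± 1.06 CPM (2.19-fold, adjusted p = 1.54e-04). Btg2, a p53 target, rose 2.25-fold, from 123 ± 12.7 to 276 ± 26.4 CPM (adjusted p = 0.00166). Ccr6, the receptor of the chemokine CCL20 and a memory B cell gene, fell 1.44-fold (adjusted p = 0.0244). Its level went from 365 ± 24.3 to 253 ± 7.29 CPM, and it was called in none of the 6 fits that left out 1 library. Ackr3, Acadl and Btg2 lie on chromosome 1 and Ccr6 in the first 20 Mb of chromosome 17, where called genes clustered. Variants carried in these stretches may underlie the differences of these genes, which therefore cannot be assigned to loss of DAF itself.

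In all, 22 of 15043 tested genes passed an adjusted p of 0.05, 12 higher and 10 lower in DAF KO (edgeR), and 988 had an unadjusted p under 0.05 where 752 would be expected by chance. Rgs18, a regulator of G protein signalling, had a log2 fold change of 2.89 (SE 0.23), from 4.70 ± 0.394 to 35.3 ± 7.30 CPM. Pam, an enzyme that amidates peptides, rose from 0.496 ± 0.105 to 5.30 ± 2.02 CPM (log2 fold change 3.44, SE 0.51). Ulk4, of the Unc-51-like kinase family, rose from 0.550 ± 0.538 to 7.74 ± 2.65 CPM (log2 fold change 3.87, SE 0.55). Among the lower genes, the centrosomal gene Cep85 fell from 428 ± 14.3 to 185 ± 10.3 CPM (log2 fold change -1.21, SE 0.07). The kinase gene Stk25 fell from 79.5 ± 1.59 to 35.7 ± 3.01 CPM (log2 fold change -1.15, SE 0.10). Changes under a doubling, named after their values were seen, included a rise of Wdfy1 (log2 fold change 0.91), Tagap1 (0.80) and Rnaset2a (0.55) and a fall of Lancl1 (-0.81) and of the mitochondrial pyruvate carrier gene Mpc1 (-0.55). The remaining called genes were 6 loci with provisional names, Gm12663, 9030025P20Rik and C130026I21Rik higher and Gm43305, Gm42031 and Gm48275 lower, also named after their values were seen. Rnaset2a, C130026I21Rik and the pseudogene Gm12663 have near-identical copies or parent genes that can share reads, so their values are uncertain.

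Calls of Acadl, Btg2, Rgs18, Ackr3, Cep85, Stk25, Gm43305 and Gm42031 held in each of the 6 fits that left out 1 library. Gm12663 was called in 3 of these fits, Cd55, Cd55b, Pam, Wdfy1, Tagap1 and Gm48275 in 1, and Ccr6, Ulk4, Mpc1, Lancl1, Rnaset2a, C130026I21Rik and 9030025P20Rik in none, always in the same direction, and limma-voom did not call Cd55b, Pam or Ulk4 (adjusted p from 0.244 to 0.378). The fits with 1 library left out called 8 to 12 genes, and DESeq2 called 88, 46 higher and 42 lower, which included all 22. With the replicate number as a block, edgeR called 10 genes, all among the 22. Cd55b, Ccr6, Ulk4 and Pam were then not called (adjusted p from 0.0819 to 0.0926).

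**Figure D1:**
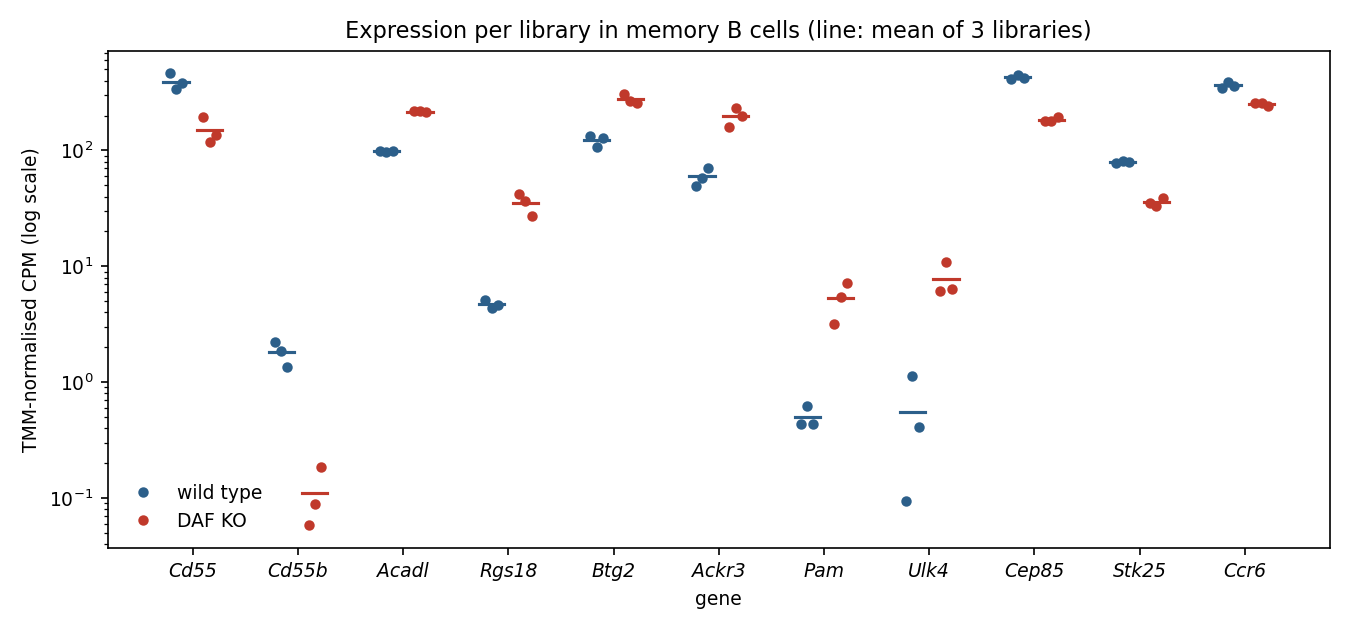
TMM-normalised CPM (log axis) of 11 genes in each library of wild-type (blue) and DAF KO (red) memory B cells, with points for the 3 libraries and a line at their mean. Every DAF KO library lies on the same side of every wild-type library for each gene shown, with Cd55 between 118 and 196 CPM in DAF KO and between 337 and 463 CPM in wild type.

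Several genes with large differences in CPM did not pass the threshold. Cxcr4, the signalling receptor of CXCL12, had 9.16 ± 1.07 CPM in DAF KO and 19.2 ± 2.59 in wild type (log2 fold change -1.08, edgeR adjusted p = 0.105). Ptprv had a log2 fold change of -1.51 (SE 0.23, adjusted p = 0.059), and edgeR called it with upper quartile factors (adjusted p = 0.0435), with a filter of at least 1 CPM in every library of a group (0.019) and without wild-type replicate 2 (0.0178). In the same order of genotypes, the kinase gene Stk16 had 23.6 ± 4.89 and 51.9 ± 11.3 CPM (called with the filter of 1 CPM, adjusted p = 0.0394), the deacetylase gene Sirt1 8.46 ± 0.458 and 17.7 ± 2.90, and Ro60 2.39 ± 1.23 and 9.04 ± 2.48. Prx had 0 counts in DAF KO and 105 in wild type, at least 35.2-fold lower against a floor of 3 counts over the group (adjusted p = 0.267). On the other side, the receptor tyrosine kinase gene Erbb3 had 14.6 ± 0.618 CPM in DAF KO and 6.45 ± 1.32 in wild type (adjusted p = 0.1). Grm6 had 5.99 ± 1.35 and 2.11 ± 0.459 CPM, Gpt2 3.02 ± 0.793 and 0.703 ± 0.0435, Bmpr1a 0.922 ± 0.0782 and 0.0327 ± 0.0311, Cntd1 0.697 ± 0.253 and 0.0931 ± 0.0408, and Vmn2r57 0.604 ± 0.0480 and 0.108 ± 0.0172. DESeq2 called Ptprv, Cxcr4, Stk16, Sirt1, Ro60, Prx, Erbb3, Grm6, Gpt2 and Bmpr1a, with adjusted p from 2.55e-08 (Ptprv) to 0.00514 (Bmpr1a).

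The called genes were unevenly placed in the genome. Chromosome 1, which carries Cd55 and also Ptprc (the CD45 gene, whose alleles mark donor cells), held 11 of the 22, among them Acadl, Lancl1, Wdfy1, Ackr3, Stk25, Pam, Btg2 and Rgs18, and 6.63% of the tested genes. These 11 lay between 66.8 and 144.8 Mb, 7 higher and 4 lower in DAF KO. Ptprc had 2230 ± 88.9 CPM in DAF KO and 1890 ± 193 in wild type (log2 fold change 0.24, edgeR adjusted p = 0.609). A list of chromosome 1 neighbours of Cd55 and Ptprc had 80 tested members, of which Rgs18 and Btg2 rose and Cd55 and Cd55b fell. Adjusted over the list alone, 7 rose and 4 fell. A shift in 1 direction was not called (median log2 fold change 0.04, camera adjusted p = 0.1), while the test for changes in either direction passed (fry mixed adjusted p = 4.22e-04). A few strongly changed members can make that test pass, and the targeted Cd55 was among them. Without DAF KO replicate 2 (median 0.04, adjusted p = 0.0248) or wild-type replicate 1 (median 0.07, adjusted p = 0.00546) the list was called higher, but not with an estimated correlation (adjusted p = 0.954 and 0.609). Ccr6, Mpc1, Tagap1, Rnaset2a and 9030025P20Rik lay between positions 6955011 and 14991572 of chromosome 17. The 6 others, Cep85, Ulk4, Gm43305, Gm42031, Gm12663 and Gm48275, were on 6 different chromosomes.

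**Figure D2:**
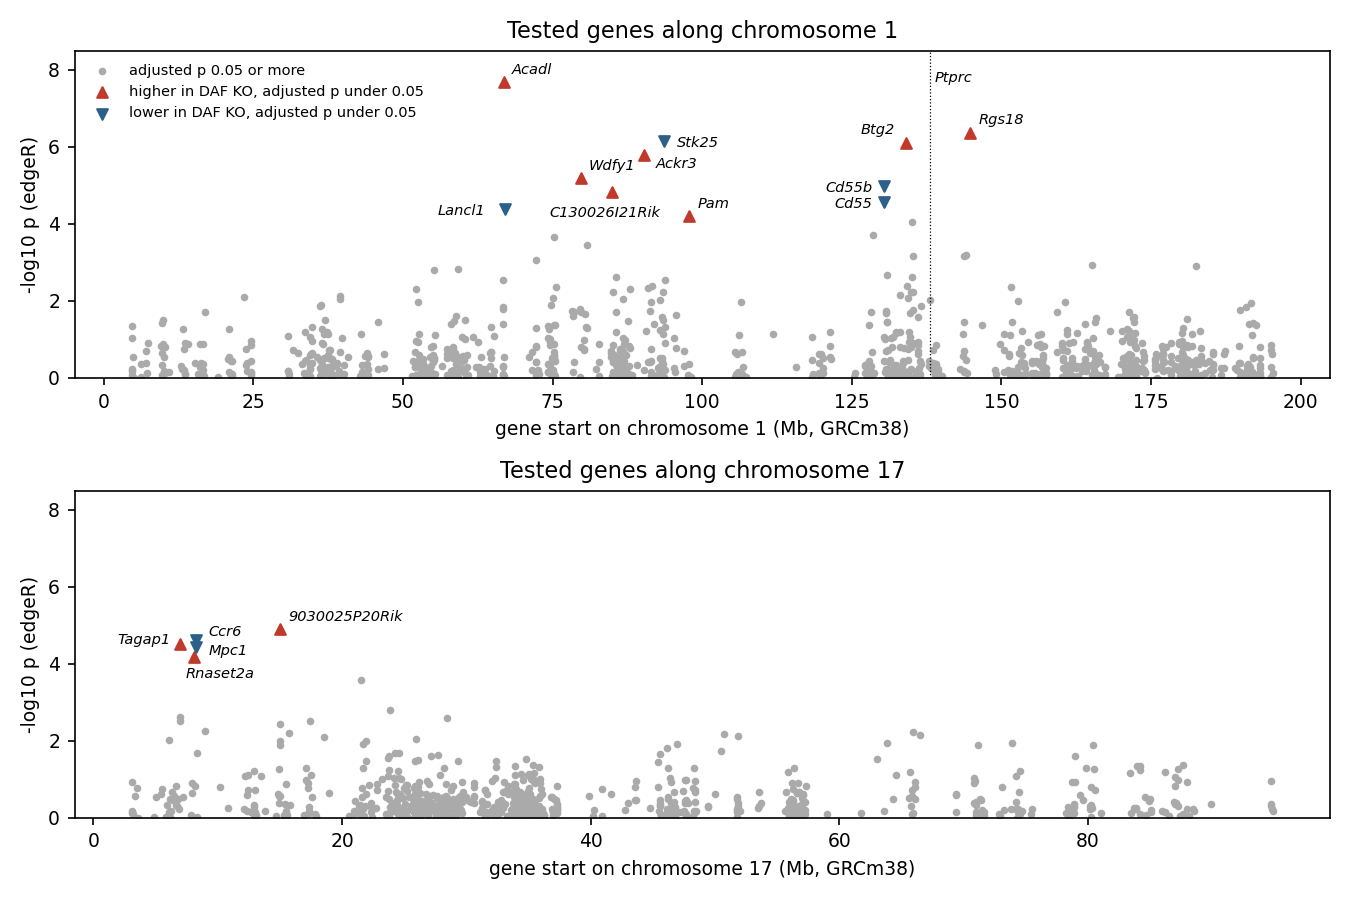
Tested genes by position on chromosomes 1 and 17 (Mb, GRCm38) against -log10 of the unadjusted edgeR p, with called genes as triangles that point up (higher in DAF KO) or down (lower) and a dotted line at Ptprc. The 11 called genes of chromosome 1 lie between 66.8 and 144.8 Mb and the 5 of chromosome 17 all lie in its first 20 Mb.

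Of 25 gene lists tested, the p53 target list alone was shifted at the preset correlation of 0.01, toward higher expression in DAF KO (camera adjusted p = 6.34e-05). That call was lost with an estimated correlation (adjusted p = 0.344) and with fry (adjusted p = 0.0766). The test for changes in either direction passed (fry mixed adjusted p = 0.00219), which 1 strongly changed member can bring about. Btg2 was its 1 called member, and 14 of its 16 tested members had a positive log2 fold change (median 0.15). Xpc, a DNA repair gene, had 50.7 ± 3.90 CPM in DAF KO and 40.2 ± 6.16 in wild type, the ubiquitin ligase gene Mdm2 146 ± 13.4 and 129 ± 5.28, and Cdkn1a, which encodes the cell cycle inhibitor p21, 0.868 ± 0.503 and 0.592 ± 0.501, examples named after their values were seen. The call also ended when chromosome 1 genes, Btg2 among them, were left out: the other 15 members had a median log2 fold change of 0.13 (unadjusted camera p of 0.006, adjusted p = 0.144).

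No shift of proliferation genes was detected. The cell cycle list had no called gene among 57 members, 36 with a negative log2 fold change (median -0.08, camera adjusted p = 0.36). Aurka, a mitotic kinase gene, had a log2 fold change of -0.72, and Dut, which acts in nucleotide metabolism, had 28.2 ± 2.52 CPM in DAF KO and 35.4 ± 1.66 in wild type. Mki67, named after its values were seen, had 3.34 ± 1.48 and 4.33 ± 1.95 CPM, with a 95% interval of its log2 fold change from -1.35 to 0.66. Without DAF KO replicate 2 the cell cycle list passed (median -0.24, adjusted p = 0.0162), but not with an estimated correlation (adjusted p = 0.954), and without DAF KO replicate 3 or wild-type replicate 2 the sign of its test turned (medians -0.02 and 0.05). Among 24 quiescence genes and cell cycle inhibitors, Btg2 rose and 19 had a positive log2 fold change (median 0.04, camera adjusted p = 0.1). Their test for either direction passed (fry mixed adjusted p = 0.00756), which 1 strongly changed member can bring about. Without DAF KO replicate 2 the list passed in camera (median 0.15, adjusted p = 0.00534), but not with an estimated correlation (adjusted p = 0.954).

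Growth and metabolism lists had no called gene. The 28 MYC and ribosome biogenesis genes had a median log2 fold change of 0.01 (camera adjusted p = 0.895), with Pprc1 at 0.30 and the chaperonin gene Hspd1 at 0.12. Medians were 0.07 for 29 mTORC1 and glycolysis genes (adjusted p = 0.36; Idi1 0.33, Hk1 0.19) and -0.03 for 32 oxidative phosphorylation genes (adjusted p = 0.361; Ndufb3 -0.23, Sdhd -0.14). Of 32 cytosolic ribosomal protein genes, 28 had a negative log2 fold change, with a median of -0.04 (adjusted p = 0.263), Rpl5 at -0.30 and Rps27 at 0.17. Without wild-type replicate 1 that list was called lower at the preset correlation (median -0.10, adjusted p = 3.69e-05) but not at an estimated one (adjusted p = 0.76), and the sign of its test turned without wild-type replicate 2 (median 0.01). The 15 mitochondrially encoded genes had a median of 0.01 (adjusted p = 0.959).

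No shift was detected in the lists of B cell identity and differentiation. Ccr6 was the only called gene among 28 memory B cell genes (median log2 fold change 0.05, camera adjusted p = 0.382, fry mixed adjusted p = 0.008). The 24 B cell identity and receptor signalling genes had a median of 0.04 (adjusted p = 0.382), with the adaptor gene Pik3ap1 at 0.19 and the IgM receptor gene Fcmr at -0.33. Medians were 0.10 for 17 germinal centre genes (adjusted p = 0.959; Nuggc -2.82, Mybl1 1.34), -0.05 for 23 plasma cell and secretory genes (adjusted p = 0.708; Ell2 0.23, Fkbp11 -0.39) and 0.08 for 16 follicular, marginal zone and B1 genes (adjusted p = 0.382; Itgb1 0.32, Bhlhe41 0.33). None of these lists other than the memory list had a called gene.

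Survival, activation and complement lists had no called gene either. The 18 anti-apoptotic and survival genes had a median log2 fold change of 0.00 (camera adjusted p = 0.777; Xiap -0.52, Tnfrsf13c, the BAFF receptor gene, 0.14), and 15 pro-apoptotic genes one of -0.02 (adjusted p = 0.959; Bid -0.13, Apaf1 0.26). Immediate early and NF-kB genes, 30 tested, had a median of 0.00 (adjusted p = 0.922), with Cd83 at 0.18 and Dusp2 at -0.39. For 35 interferon response genes the median was 0.05 (adjusted p = 0.777; Gbp7 0.25, Dhx58 0.23). The 18 tested genes of complement and its receptors had a median of 0.07 (adjusted p = 0.959), with C4a at -2.06, whose reads C4b can share, and the complement receptor gene Itgax at 1.06. Adjusted over the list alone, each list other than the chromosome 1 neighbours had as many called genes as over all genes tested. Medians and camera differed in sign for the mitochondrially encoded and pro-apoptotic lists, as they did for the T cell, NK cell and dendritic cell markers, and the germinal centre mean was -0.07.

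**Figure D3:**
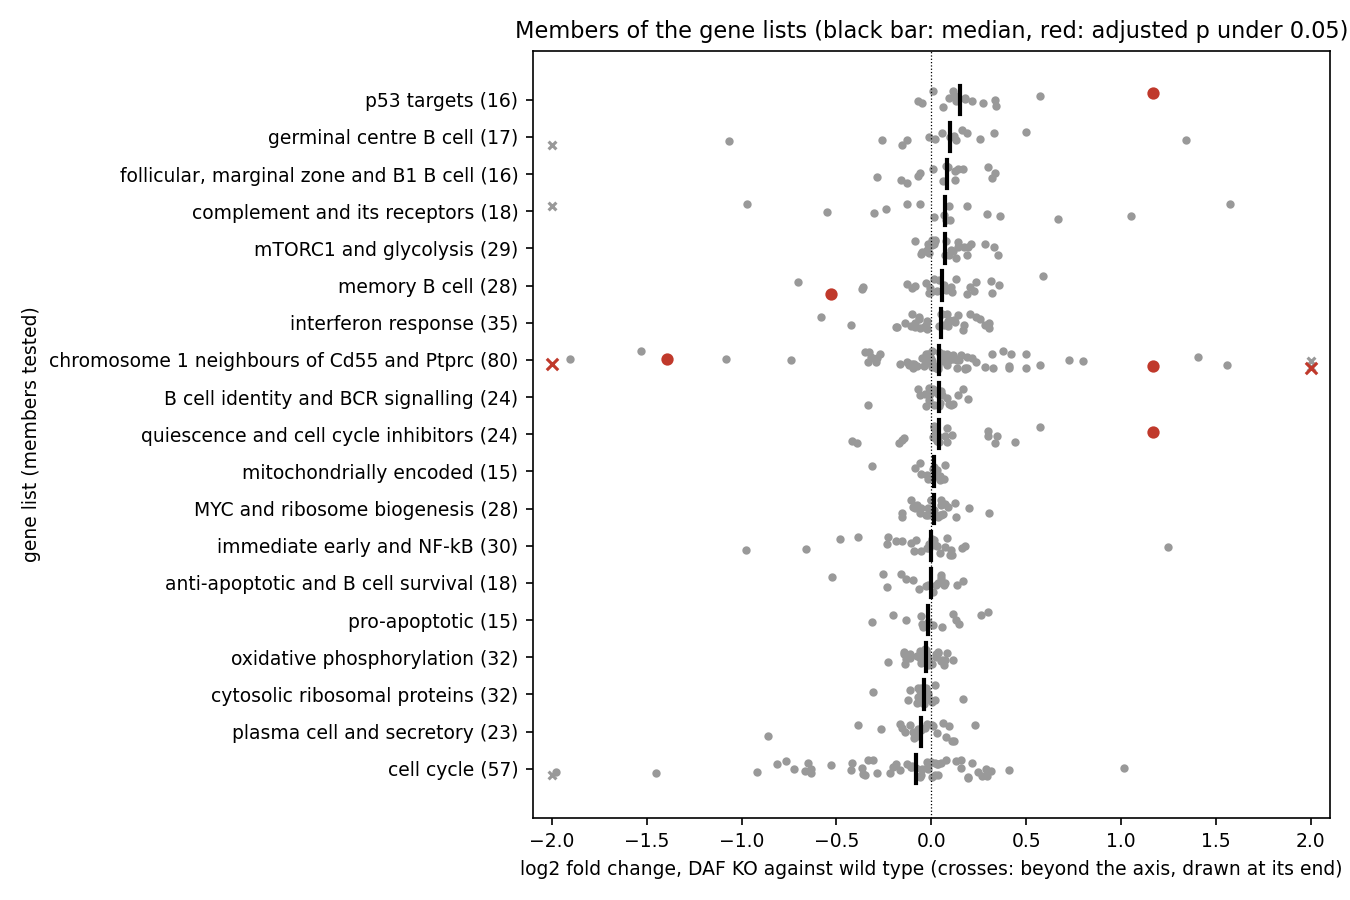
log2 fold change (DAF KO against wild type) of each tested member of 19 gene lists, with a black bar at the list median, red for adjusted p under 0.05 and crosses at the axis ends for members beyond them. The p53 target list has the highest median, 0.15, with Btg2 in red.

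Markers of other cell types were mostly low, and none of the lists passed the test between the genotypes with all libraries. Cd3e, a T cell receptor subunit, reached at most 0.165 CPM and the NK cell receptor gene Ncr1 had no count. Summed markers were 297 ± 19.6 CPM in DAF KO and 281 ± 6.56 in wild type for T cells, 47.1 ± 3.26 and 44.4 ± 1.70 for NK cells, 118 ± 13.7 and 104 ± 24.3 for myeloid cells, 86.0 ± 6.48 and 80.2 ± 12.9 for dendritic cells, and 257 ± 20.5 and 238 ± 31.8 for stromal and endothelial cells. Most of the T cell sum was Cd2 (241 to 271 CPM) and most of the stromal sum Pecam1 (200 to 279 CPM), both of which B cells express. Prf1 contributed 41.1 to 46.9 CPM to the NK cell sum. Neutrophil markers summed to at most 0.248 CPM. The erythroid and platelet sum was 42.2 CPM in DAF KO replicate 1 and 7.01 to 15.0 CPM in the other 5 libraries. Camera adjusted p was 0.875 for T cell, 0.361 for myeloid, 0.777 for NK cell, 0.708 for erythroid and 0.959 for dendritic cell markers, and the neutrophil and stromal lists had too few tested members. Without wild-type replicate 1 the myeloid list was called higher in DAF KO (median log2 fold change 0.52, adjusted p = 0.00546), but not with an estimated correlation (adjusted p = 0.609). Sex-linked genes gave an adjusted p of 0.708 (median log2 fold change -0.39).

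The antibody repertoire was read from immunoglobulin transcripts, which count RNA and not cells or clones. Ighv1-72, the canonical heavy chain variable gene of the mouse response to NP, took 85.4% ± 3.59 of heavy chain variable counts in DAF KO and 80.3% ± 2.29 in wild type (SD, n = 3 each, exact two-sided permutation p = 0.2). The Ighv1-72 share was each time higher in DAF KO than in the wild-type library of equal number, and no paired test was run. The effective number of heavy chain variable genes, the exponential of their Shannon entropy, was 2.23 ± 0.342 in DAF KO and 2.81 ± 0.191 in wild type. All 3 DAF KO libraries lay below the 3 wild-type libraries, and the exact permutation p of 0.1 is the smallest that 3 against 3 libraries allow. It was 0.75 after adjustment over 12 immunoglobulin measures. With variable genes limited to those with 10 counts in every library, the differences were 1.22 percentage points and -0.08. That limit also dropped genes abundant in 1 library and nearly absent from others, which are part of the diversity measured. Of 7 genes with at least 1% in 1 library and at least 10 times the median of the other 5, it removed 4. Among these were Ighv6-6 (6.33% in wild-type replicate 1) and Ighv6-3 (3.71% in DAF KO replicate 2). The smaller differences therefore do not show that low counts made the full ones. The libraries held 27865 to 42320 heavy chain variable counts.

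No difference in isotype composition was detectable with libraries treated as unpaired. Between libraries of equal number, the shares of Ighg2b and Ighg2c were always higher and that of Ighg3 always lower in DAF KO. The other isotypes went both ways, and no paired test was run. Ighm, the IgM constant gene, took 70.6% ± 0.728 of heavy chain constant counts in DAF KO and 71.9% ± 1.77 in wild type (exact permutation p = 0.4, n = 3 each). Ighg1 took 11.4% ± 2.30 and 10.7% ± 1.35, Ighd 11.1% ± 3.44 and 10.4% ± 2.35, Ighg3 3.29% ± 0.184 and 3.51% ± 0.317, and Ighg2b 3.02% ± 0.738 and 2.62% ± 0.744. Igha took 0.617% ± 0.618 and 0.872% ± 0.874, Ighg2c 0.0615% ± 0.0226 and 0.0465% ± 0.0159, and Ighe 0.0136% ± 0.00986 and 0.0122% ± 0.00920. Lambda constant genes made up 91.5% ± 0.496 of light chain constant counts in DAF KO and 90.2% ± 1.82 in wild type, after a sort on lambda light chain. Iglv1 took 82.7% ± 1.30 and 81.6% ± 2.21 of lambda variable counts. Exact permutation p lay between 0.4 and 1 for these isotype and light chain measures, and none of the genes was called by edgeR.

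**Figure D4:**
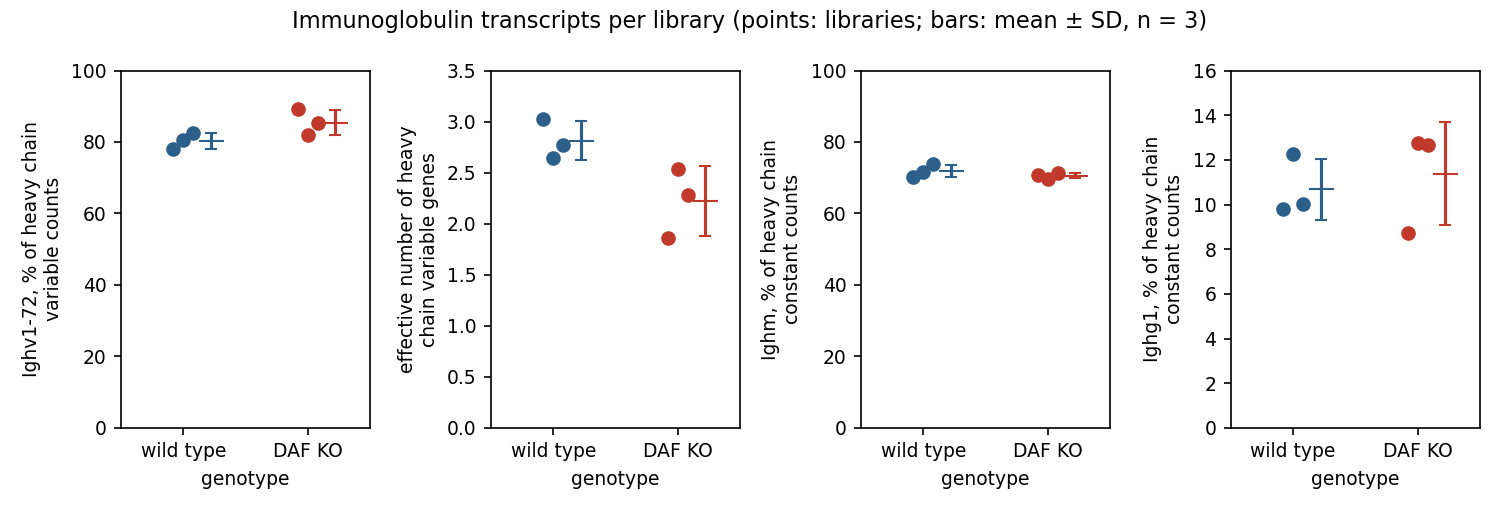
Share of Ighv1-72 among heavy chain variable counts (%), effective number of heavy chain variable genes, and shares of Ighm and Ighg1 among heavy chain constant counts (%) in wild-type (blue) and DAF KO (red) libraries, with points for libraries and bars for mean ± SD. The effective number lies between 1.86 and 2.54 in DAF KO and between 2.65 and 3.02 in wild type.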

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

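Settings that left out all of chromosome 1, alone or with the first 20 Mb of chromosome 17, were chosen after the result was seen. The 22 calls (12 higher, 10 lower) were 19 to 27 with RLE or upper quartile factors, other count filters, robust=FALSE or no immunoglobulin genes, and 17 with limma-voom or without the chromosome 1 neighbour list. DESeq2 called 88 genes (46 higher, 42 lower), which included the 22, and 27 of its calls were on chromosome 1. Leaving out 1 library gave 8 to 12 calls (4 to 7 higher, 4 to 6 lower), with fewer samples, and 8 of the 22 genes were called in all 6 such fits and 7 in none. With the replicate number as a block there were 10 calls (5 higher, 5 lower), all among the 22, and 2 lists shifted, the second being quiescence genes (median 0.06, adjusted p = 0.0345, and 0.871 with an estimated correlation). Cd55b, Ccr6, Ulk4 and Pam were not called under the block (adjusted p from 0.0819 to 0.0926), nor were Cd55b, Ulk4 and Pam by limma-voom (0.244 to 0.378). Pam also missed the threshold without a count filter (0.0537), with robust=FALSE (0.0506) and without the chromosome 1 neighbour list (0.0515). Calls were gained for Ptprv with upper quartile factors (0.0435), the 1 CPM filter (0.019) and without wild-type replicate 2 (0.0178), and for Stk16 with the 1 CPM filter (0.0394). The numbers were not treated as a pairing: same-numbered libraries deviated together with r = 0.146, 0.153 and 0.046 across 5874 genes, under the limit of 0.1 for number 3, although every library correlated best with its own number across these genes. Across all 15043 tested genes that did not hold: DAF KO 3 correlated best with wild type 2 (0.028) and wild type 3 with DAF KO 1 (0.027). Of the 11 calls off chromosome 1, 7 were left when its genes were not tested (2 higher, 5 lower), and of the 6 off chromosomes 1 and 17, 5 without the chromosome 17 stretch too (1 higher, 4 lower). Ulk4 was still tested and lost its call in both settings (adjusted p = 0.0693 and 0.113). No list was shifted (0) in these 2 settings, without the chromosome 1 neighbour list, with an estimated correlation, or with fry. The p53 target median was then 0.1288 in both chromosome settings, 0.1295 without the neighbour list, and 0.1521 with an estimated correlation or fry. Leaving out 1 library gave 1 to 4 shifted lists, myeloid markers among them without wild-type replicate 1 (0.00546, and 0.609 with an estimated correlation), and p53 targets were shifted in all 6 fits at the preset correlation and in none at an estimated one (adjusted p from 0.387 to 0.97). The Cd55 log2 fold change ran from -1.631 to -1.248 with 1 library out, losing its call without DAF KO replicate 2 (-1.25) or 3 (-1.33) or wild-type replicate 1 (-1.26), 2 (-1.50) or 3 (-1.42). Those of Cd55b, Pam, Ulk4 and Ccr6 lay between -4.60 and -3.73, 3.14 and 3.68, 3.27 and 5.05, and -0.57 and -0.48. The cell cycle median ran from -0.2399 (without DAF KO replicate 2, called) to 0.05015 (without wild-type replicate 2), and that of ribosomal protein genes from -0.1022 (without wild-type replicate 1, called) to 0.007847 (without wild-type replicate 2). Signs turned among uncalled immunoglobulin genes, with log2 fold changes with 1 library out from -0.163 to 0.3983 for Ighd, -0.06182 to 0.0002513 for Ighg3, -0.00141 to 0.04071 for Iglv1, -0.3986 to 0.921 for Ighe, -1.752 to 0.8289 for Igha and -0.002624 to 0.05725 for Ighm. Limiting variable genes to those with 10 counts in every library moved the Ighv1-72 difference to 1.224 points and that of the effective number to -0.08097. Without DAF KO replicate 1 the Ighv1-72 difference was 3.28 points. The difference of the Ighm share ran from -2.142 to -0.3873 points with 1 library out. For the other changes the cause was not tested. Of 1116 comparisons of named genes and lists other than Cd55, p53 targets and cell cycle, whose changes are given above, 1055 kept direction and side of the threshold. Depth limits genes under about 1 CPM, such as Bmpr1a and, in DAF KO, Cd55b.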

Other observations

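Tests on gene position and on the Cd55 RNA left in DAF KO, and the handling test for p53 targets, were chosen after the results were seen.

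Single libraries carried heavy chain variable genes that the others nearly lacked, in a response dominated by Ighv1-72. A gene was counted as private when it took at least 1% of heavy chain variable counts and at least 10 times the median of the other 5 libraries, and 7 genes in 5 libraries did. Ighv10-1 took 7.37% in wild-type replicate 2 against a median of 0.268% elsewhere, and Ighv6-6 took 6.33% and Ighv5-17 3.66% in wild-type replicate 1. Wild-type replicate 3 held Ighv1-26 at 2.37%. In DAF KO, Ighv6-3 (3.71%) and Ighv1-22 (2.95%) stood out in replicate 2 and Ighv10-3 (3.27%) in replicate 3, while DAF KO replicate 1 had none. Xist had 180 and 176 CPM in replicate 2 of DAF KO and wild type and 66.1 to 90 CPM in the other libraries. The Y-linked Ddx3y had 30.2 and 36.2 CPM there against 90.1 to 136 elsewhere. Ighd took 15.0% and 13.1% of heavy chain constant counts in replicate 1 of DAF KO and wild type. Its share was 8.87% to 9.29% in the other libraries. Libraries of equal number may therefore share recipient pools, although no label pairs them. The 22 calls treat them as unpaired, and 10 genes were called with the replicate number as a block.

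The number of changed genes, 22, was compared with other groupings of the 6 libraries. Only 1 of the 10 splits into 3 and 3, the real one, gave as many, and the highest of the others gave 0. With 10 splits the share cannot fall under 0.05.

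Changed genes clustered by position: 11 of 22 were on chromosome 1 (Fisher's exact p = 3.69e-08). The odds ratio for chromosome 1 was 14.2. That placement argues against loss of DAF acting alike on genes wherever they lie as the whole cause. It leaves the 11 other genes open. The odds ratio and its p include the targeted gene Cd55 and its neighbour Cd55b, and the 9 other chromosome 1 calls were not tested apart. A candidate explanation is variants carried with the targeted Cd55 locus and the donor Ptprc alleles. Among 76 uncalled members of the neighbour list fixed beforehand, 21.1% had an unadjusted p under 0.05. Among uncalled genes off chromosomes 1 and 17 the share was 6.10% (Fisher's exact p = 1.28e-05). Of the called genes, that list holds only Rgs18, Btg2, Cd55 and Cd55b. Acadl, Lancl1, Wdfy1, C130026I21Rik, Ackr3, Stk25 and Pam start between positions 66830839 and 97795114, outside the list, so the test does not cover them. Reads of non-reference alleles lost in mapping stay open, since 77.8% of the called chromosome 1 genes other than Cd55 and Cd55b were higher in DAF KO and the strain of each donor stretch is not given. A second stretch of variants may lie in the first 20 Mb of chromosome 17, with 5 of the 11 other calls, where uncalled genes also had an unadjusted p under 0.05 more often (12.1% of 91 against 6.10%, Fisher's exact p = 0.0263), although with any 1 library left out at most Tagap1 of the 5 was still called.

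The p53 target list was called higher in DAF KO at the preset correlation but not at an estimated one (adjusted p = 0.344) or with fry (0.0766). Its fry test for either direction passed (adjusted p = 0.00219), which 1 strongly changed member can bring about, and its called member Btg2 lies on chromosome 1. Without chromosome 1 the median log2 fold change went from 0.152 (quartiles 0.086 and 0.287) to 0.129 (quartiles 0.078 and 0.243), 13 of 15 members stayed positive, and the unadjusted camera p was 0.006. The call ended (adjusted p = 0.144), with Btg2 the only tested member left out. The p of 0.006 rests on the preset correlation and was 0.0991 with an estimated one. The estimated version is the weaker test, so the higher p does not show that members are correlated. Without DAF KO replicate 1 the estimated correlation was -0.023, below the preset 0.01, yet adjusted p went from 9.14e-05 to 0.387. With these versions in conflict, a shift due to Btg2 alone and a wider p53 response (median 0.129 off chromosome 1) cannot be told apart in these libraries. Stress from sorting, which raises immediate early genes, also stays open: their median was -0.003 with members on both sides of 0.

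Cd55 RNA at 38.1% of the wild-type level remained in DAF KO. Wild-type cells in the DAF KO sort would bring Cd55b along at a like share, and Cd55b stood at 6.09% (3.21% to 10.2% in single libraries). Over the DAF KO libraries Cd55b had 19 counts where a share of 38.1% would bring 116.8. Prx had 0 counts where that share would bring 40.3, but it was named for being low in DAF KO, so it cannot count against such cells. Wild-type cells stay open, since the low Cd55b value does not decide it: Cd55b had 3 to 11 counts per DAF KO library and can share reads with Cd55. Prx was rarer still in wild type, and none (0) of 15043 tested genes lay below 38.1% of wild type after adjustment. Transcript from exons outside the deletion may account for the 38.1%, but gene-level counts do not resolve exons.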
